A study of Oryza sativa with 12 samples.

How the data were processed

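RNA from the middle part of rice flag leaves (cultivar 996) was measured at 6 times of heat at 40 °C, 0 min, 20 min, 1 h, 2 h, 4 h and 8 h, with 2 arrays per time from independent replicate experiments. Per the labels, plants were grown in the field, kept in pots in a growth chamber at 32 °C by day and 28 °C by night for 1 day and then moved to heat, and Cy3-labelled cRNA was made from 2 µg RNA with a low-input linear amplification kit. The arrays were Agilent 1-colour rice arrays of design 015241. Per the file headers, Feature Extraction 9.5.3.1 read the scans with protocol GE1-v5_95_Feb07, and the authors deposited its output, in which each spot has a mean signal, a background and a processed signal in units of intensity. Each array had 45151 spots, of which 1417 were controls, and the other 43734 held 42477 probes, 41889 of them with a locus number of 29689 loci.

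The authors also deposited a value table in log2 units whose scale was not stated. Its unit and direction were found by comparison: each probe had a median of 0 over the 12 columns to within 1.0e-06, and against quantile-normalized log2 processed signal with the same centring the slope was 0.9998 and the correlation across probes 0.9999 over 42475 probes. Higher values therefore stand for more signal, the level of a probe cannot be read from it, and its column medians ran from -0.03425 to 0.0218. The tool that made the table is not known, and the table was used only as an alternative.

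For the values reported, spots that Feature Extraction called outliers were left out (61 to 118 per array) and replicate spots of a probe were averaged on the log2 scale. The processed signal was taken to log2, and each array's 75th percentile was subtracted. A probe was kept if it was well above background on both arrays of at least 1 time, which left 34437 probes, and a gene was read from its kept probe with the highest mean signal, which left 23595 genes. Between 65.3 and 79.6% of spots were well above background, with the lowest shares on the third slide (65.3 to 68.4%), and 1 to 34 spots per array were saturated. Where a time was not well above background or was saturated, a bound is given. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, and a saturated signal counts as measured. Gene names and descriptions came from the files, since 0 of the loci matched the reference table.

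All 12 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes) with the 6 times as groups, no covariate, 6 residual and 2.243 prior degrees of freedom, and 74 genes with a missing value. The limma tests were two-sided, with Benjamini-Hochberg adjustment over genes within each of 8 comparisons, and a gene was called at an adjusted p under 0.05. These were each heat time against 0 min, 2 h against 1 h and 8 h against 4 h within a slide, and 8 h against 20 min; limma's moderated F-test over the 5 differences from 0 min gave the overall count. Of 32 gene lists, each with 3 or more measured genes, camera tested the shift against all other genes with a preset correlation of 0.01, and with an estimated correlation as an alternative. Named genes were taken from the 6 highest and the 6 lowest called genes with a functional name whose arrays did not overlap, the 4 members of a list with the largest change, any member of a list of up to 25 measured genes and 8 genes followed at every time. Not every gene under this rule is named. Those of the 6 highest or lowest that lost their call with 1 array left out are not, a step outside the rule. The groups, comparisons, tests, lists, named-gene rule and alternatives were set before the data were examined, apart from those said below to be chosen after. Other software was data.table (1.17.8), jsonlite (2.0.0), Python (3.11.15), matplotlib (3.10.9) and pandas (2.3.3).

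The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, scaling on the median, the authors' value table, no filter on dim probes, only probes well above background on all 12 arrays, the mean of a gene's probes, outlier-flagged spots kept, the replicate number as a block, a trend and robust prior, a fit to only the 4 arrays compared, an added 2-fold threshold, camera with an estimated correlation, and each array left out in turn. Scaling on spike-in spots was not run, because the control spots lay near background (medians 7.771 to 64.1, with 0.938 to 30.3% well above it). A slide term was not fitted, since each time lay on a single slide. The pipeline was tested on 12 simulated arrays built on each gene's mean over all arrays and its spread within the 6 times. In each of 20 runs, 200 genes per size were changed on the 20 min arrays and tested against 0 min. Limma then recovered 4.22% of changes of 0.5, 42.4% of changes of 1 and 78.8% of changes of 2 on the log2 scale, with 5.54% of its calls on unchanged genes. With so few changed genes a change of 0.5 was mostly missed. In the data 10481 of 23595 genes were called at 20 min, which makes the adjusted threshold less strict. The simulated recovery is therefore not the detection limit of these data. Camera called 100% of shifted and 0% of unshifted lists of 50 genes. The simulated genes were drawn independently, so this cannot show how camera treats lists of correlated genes. Probes named for microRNAs have no locus number and were fitted apart from the genes.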

Results

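The transcripts of rice flag leaves were measured on 12 one-colour arrays over 8 h of heat. Middle parts of flag leaves of cultivar 996, which the labels call heat tolerant, were taken at the reproductive stage after 0 min, 20 min, 1 h, 2 h, 4 h and 8 h at 40 °C. Each of the 6 times had 2 arrays from independent replicate experiments, and the 0 min arrays were the only control. One label names spikelets as the stage while the others name the flag leaf. The arrays filled 3 slides of 4 arrays, with 0 min and 20 min on the first, 1 h and 2 h on the second, and 4 h and 8 h on the third. The comparisons of 20 min with 0 min, 2 h with 1 h and 8 h with 4 h stayed within a slide, while in all the others slide and heat time cannot be told apart. Time of day also moved with heat time, as the control leaves were taken at the start. Between 65.3 and 79.6% of the spots of an array were well above background, and the 75th percentile of its signal lay between 4059 and 11660. Values are log2 fold changes of processed signal ± their standard error from limma with 2 arrays per group, and the number of arrays limits their precision. For every gene named below as changed, both arrays of one time lay beyond both arrays of the other. Limma's p-values weigh a change against the spread between the 2 arrays of a time, which shared a slide. The spread between slides is not in them, so they may be too small for comparisons across slides and for the F-test. Of the alternatives, normexp with quantile normalization, quantile normalization of the processed signal and the authors' value table are called the 3 quantile scalings. Counts of a list's genes are over its measured members, and camera's calls used a preset correlation of 0.01. With a correlation estimated for each list it called 0 lists in any of the 8 comparisons (lowest adjusted p = 0.166), against 7 of 32 at an unadjusted p under 0.05 at 20 min.

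Most of the measured transcripts changed over the 6 times. Of 23595 genes with a probe well above background, 20489 (86.9%) passed limma's moderated F-test over the 6 times. Replicate arrays correlated at 0.9772 to 0.9915 across genes, which are not independent of each other. Their median SD was 0.129 to 0.201 on the log2 scale. Arrays of 20 min and 1 h, on different slides, correlated at 0.966 to 0.976, and those of 1 h and 2 h, on the same slide, at 0.930 to 0.941.

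**Figure D1:**
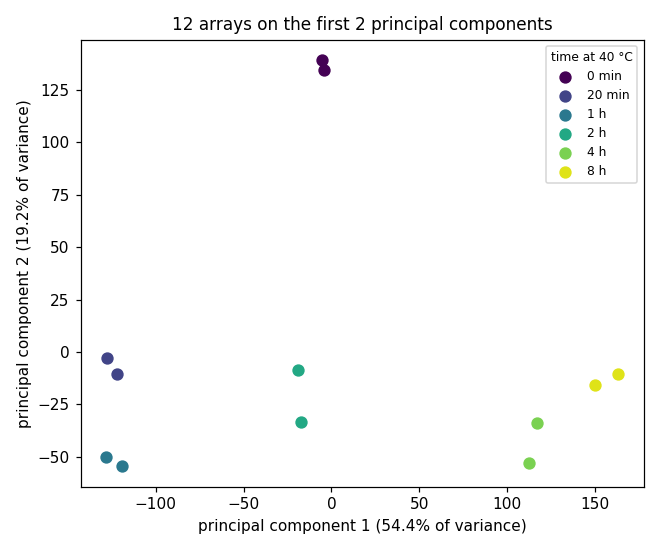
Principal components of the 12 arrays from the log2 levels of all genes without a missing value, with 1 point per array and 1 colour per time. PC1, with 54.4% of the variance, separated the 20 min and 1 h arrays from the 4 h and 8 h arrays, and PC2, with 19.2%, separated the 0 min arrays from the rest.

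Within 20 min at 40 °C, transcripts of heat shock proteins, which keep other proteins folded, rose to some of the largest fold changes on the array. An Hsp20-type gene (Os02g0711300) rose by 12.39 ± 0.45, HSP26 (Os03g0245800), a small heat shock protein, by 12.02 ± 0.24 and HSP81-1 (Os04g0107900), of the HSP90 family, by 11.89 ± 0.50. The comparison asked what had changed first, and both times lay on 1 slide. Of the small heat shock proteins, 21 of 27 rose, 2 fell and 4 did not pass (21 and 2 adjusted over the list alone, median 4.62, camera adjusted p = 8.69e-12). Those that rose included genes for a class IV protein (Os04g0445100, 11.34 ± 0.68) and a class I protein (Os01g0136100, 10.14 ± 0.43). In the HSP70 family, which folds new and damaged proteins with the help of ATP, 10 of 16 rose, 1 fell and 5 did not pass (10 and 1 adjusted over the list alone, median 1.21, camera adjusted p = 1.81e-04). Its members Os05g0460000 and Os03g0277300 rose by 8.81 ± 0.56 and 7.43 ± 0.48. In the HSP90 family 5 of 6 rose and 1 fell (5 and 1 adjusted over the list alone, median 2.79, camera adjusted p = 0.00201); the median was 1.74 to 1.76 under the 3 quantile scalings. Of the HSP100 and ClpB genes, which pull proteins out of aggregates, 3 of 3 rose (3 adjusted over the list alone, median 5.12, camera adjusted p = 9.79e-04). ClpB (Os02g0181900) rose by 5.12 ± 0.22 and HSP101 (Os05g0519700), saturated at 20 min, was at least 36.3-fold higher. Among the chaperonins, barrel-shaped folding machines, 16 of 28 rose, 3 fell and 9 did not pass (16 and 3 adjusted over the list alone, median 1.32, camera adjusted p = 1.81e-04); the median was 0.81 under normexp with quantile normalization. The co-chaperonin genes CPN10 (Os07g0641700) and a GroES-like protein (Os04g0372700) rose by 4.29 ± 0.23 and 5.36 ± 0.45. For the genes named as changed in this paragraph the highest adjusted p was 6.36e-05.

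Genes that regulate or accompany the heat response rose as well. Of the heat shock factors, the transcription factors that switch on heat shock genes, 18 of 23 rose, 1 fell and 4 did not pass (19 and 2 adjusted over the list alone, median 2.05, camera adjusted p = 6.07e-10). The 1 that fell encodes a protein that binds heat shock factors (Os06g0274000, -0.58 ± 0.13). Among those that rose were Os06g0565200 (11.69 ± 0.26), a gene described as Spl7 (Os04g0568700, 6.95 ± 0.31) and RHSF2 (Os08g0546800, 5.31 ± 0.23). Of the genes for folding in the endoplasmic reticulum, 9 of 15 rose, 1 fell and 5 did not pass (9 and 1 adjusted over the list alone, median 1.63, camera adjusted p = 0.0019), with a median of 0.95 to 0.96 under the 3 quantile scalings. Calnexin (Os04g0402100) rose by 2.98 ± 0.23 and the luminal chaperone BiP (Os05g0367800) by 2.90 ± 0.33. The JAZ list was drawn by the letters ZIM or TIFY in a gene's description and mostly holds JAZ repressors of jasmonate signalling. In it 9 of 14 rose and 5 did not pass (10 adjusted over the list alone, median 1.65, camera adjusted p = 1.92e-04). Os10g0391400 rose by 5.10 ± 0.54 and Os03g0181100 by 4.65 ± 0.41, while the list also held a gene described as a potassium channel, which lets ions through membranes (Os07g0108800, 3.36 ± 0.34). Potassium channel genes caught by this search are counted in every result of the list, which was not tested without them. A gene with a calmodulin-binding IQ region (Os11g0506800) was also among the largest rises, at 11.55 ± 0.56. Trehalose-phosphatase (Os03g0386500), which makes the sugar trehalose, rose by 6.34 ± 0.26 and raffinose synthase (Os01g0170000), for a protective sugar of the raffinose series, by 5.14 ± 0.31. In their list, galactinol, raffinose and trehalose synthesis, 5 of 12 rose, 4 fell and 3 did not pass (5 and 4 adjusted over the list alone, median 0.24, camera adjusted p = 0.334). Over the alternatives that median ran from 0.023 to 0.39. Of the 6 lowest genes, a peroxidase (Os10g0109300) fell by 4.76 ± 0.72 and an ankyrin repeat protein (Os07g0436100) by 4.60 ± 0.70. The rest of the 6, with changes of -7.53 to -4.69, lost their call with 1 array left out and are not named. The highest adjusted p of the changed genes named here was 0.00772.

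Several other groups were called by camera at 20 min, but their calls depended on the scaling, the probe filter or 1 array. Of the antioxidant enzymes, 23 of 43 rose, 4 fell and 16 did not pass (23 and 5 adjusted over the list alone, median 0.57, camera adjusted p = 3.95e-04), and the call ended under the 3 quantile scalings (medians 0.053 to 0.076, adjusted p 0.0999 to 0.116). The Cu/Zn superoxide dismutase gene Os07g0665200, whose enzyme removes superoxide, rose by 3.11 ± 0.29. Of the leaf senescence genes, 4 of 13 rose, 1 fell and 8 did not pass (4 and 1 adjusted over the list alone, median 0.84, camera adjusted p = 0.0281), and that call ended under no filter on dim probes and without 0 min replicate 1 and 20 min replicate 2 (medians 0.77 to 0.84, adjusted p 0.0537 to 0.0575). Of the light harvesting and photosystem genes, 21 of 46 rose, 2 fell and 23 did not pass (25 and 3 adjusted over the list alone, median 0.59, camera adjusted p = 1.81e-04), a direction that turned under the 3 quantile scalings (medians -0.12 to -0.10, adjusted p 0.795 to 0.817). Camera called no shift in 4 further groups, and the median of each turned sign with the scaling, for DnaJ co-chaperones under scaling on the median and for the other groups under the 3 quantile scalings. Those of immunophilins and cell wall genes also turned without 0 min replicate 2, and that of cell wall genes with only probes well above background on all 12 arrays. In DnaJ co-chaperones 20 of 79 rose, 20 fell and 39 did not pass (23 and 20 adjusted over the list alone, median -0.072, mean 0.31, test upward, camera adjusted p = 0.599), although the DnaJ gene Os01g0606900 rose by 11.52 ± 0.37. For immunophilins and co-chaperones, 10 of 43 rose, 5 fell and 28 did not pass (10 and 4 adjusted over the list alone, median 0.021, camera adjusted p = 0.331), with FKBP12 (Os04g0352400) at 5.11 ± 0.50. Of the glutathione S-transferases, which detoxify by conjugation, 10 of 51 rose, 8 fell and 33 did not pass (9 and 7 adjusted over the list alone, median 0.15, camera adjusted p = 0.331), with GST1 (Os01g0371200) at 5.20 ± 0.75. Of the cell wall genes, 21 of 106 rose, 22 fell and 63 did not pass (21 and 22 adjusted over the list alone, median 0.016, mean -0.18, test upward, camera adjusted p = 0.83). The changed genes named here had adjusted p up to 9.03e-04.

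In all, limma called 4728 genes higher and 5753 lower at 20 min than at 0 min with a Benjamini-Hochberg adjusted p under 0.05, of which 3223 and 2997 changed at least 2-fold. The count of lower genes was 3746 without 0 min replicate 1 and 3801 without 20 min replicate 2. Camera called 15 lists higher; it called 0 lower, also at an unadjusted p under 0.05. Quantile normalization, and the authors' value table with it, shifted the median of all genes by -0.10 here.

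By 1 h the heat shock genes were still far above their 0 min level. HSP26 (Os03g0245800) rose by 12.31 ± 0.24, the class I small heat shock gene Os01g0136100 by 11.71 ± 0.43 and HSP81-1 (Os04g0107900) by 11.76 ± 0.50. The comparison asked what differed after the first hour of heat. Among small heat shock proteins 22 of 27 rose, 1 fell and 4 did not pass (22 and 1 adjusted over the list alone, median 4.82, camera adjusted p = 3.26e-11). Of the heat shock factors 19 of 23 rose, 3 fell and 1 did not pass (19 and 4 adjusted over the list alone, median 2.31, camera adjusted p = 1.10e-06), with Os06g0565200 at 11.03 ± 0.26. In the HSP70 family 10 of 16 rose, 3 fell and 3 did not pass (10 and 4 adjusted over the list alone, median 1.66, camera adjusted p = 0.00192). In the HSP100 and ClpB list 3 of 3 rose (3 adjusted over the list alone, median 5.08, camera adjusted p = 0.00236), with ClpB (Os02g0181900) at 5.15 ± 0.22. Of the chaperonins 19 of 28 rose, 4 fell and 5 did not pass (19 and 5 adjusted over the list alone, median 1.55, camera adjusted p = 5.80e-05), with CPN10 (Os07g0641700) at 4.62 ± 0.23 and CPN60-1 (Os10g0462900) at 4.34 ± 0.22. Of the endoplasmic reticulum folding genes 10 of 15 rose, 1 fell and 4 did not pass (10 and 1 adjusted over the list alone, median 2.25, or 1.97 with bounds, camera adjusted p = 6.72e-04), with the calcium-binding chaperone calreticulin (Os03g0832200) at 4.61 ± 0.69 and protein disulfide isomerase (Os02g0554900), which pairs cysteines, at 4.10 ± 0.39. The highest adjusted p among the changed genes of this paragraph was 8.14e-04.

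Most genes of the JAZ, WRKY, DREB, and LEA and dehydrin lists also rose by 1 h. In the JAZ list 9 of 14 rose and 5 did not pass (9 adjusted over the list alone, median 1.82, camera adjusted p = 0.00236), with Os10g0391400 at 6.64 ± 0.54 and Os03g0181100 at 5.44 ± 0.41; the median was 3.13 under only probes well above background on all 12 arrays. Of the WRKY factors, often part of defence responses, 32 of 60 rose, 10 fell and 18 did not pass (33 and 10 adjusted over the list alone, median 1.00, camera adjusted p = 0.0016), with WRKY28 (Os06g0649000) up by 5.07 ± 0.51 and WRKY50 (Os11g0117600) at -5.51 ± 1.18; the median was 0.60 under normexp with quantile normalization. Of the DREB factors, regulators of dehydration and cold genes, 10 of 11 rose and 1 did not pass (10 adjusted over the list alone, median 1.23, camera adjusted p = 0.00175), with the gene Os09g0522000 at 3.41 ± 0.74, and the median was 0.77 under normexp with quantile normalization. Of the LEA proteins and dehydrins, which protect drying cells, 12 of 20 rose, 2 fell and 6 did not pass (13 and 2 adjusted over the list alone, median 1.67, or 1.60 with bounds, camera adjusted p = 0.00174), with the dehydrin COR410 (Os02g0669100) at 4.87 ± 0.38. Their call ended under only probes well above background on all 12 arrays (median 0.94, adjusted p = 0.131), and the median was 0.97 under normexp with quantile normalization. A gene for a bHLH regulator (Os01g0108400) was among the lowest, at -5.86 ± 1.10. Limma called 5688 genes higher and 7111 lower (4117 and 3814 at least 2-fold), and camera called 16 lists higher and 0 lower, with 0 lower at an unadjusted p under 0.05. The highest adjusted p of the changed genes named here was 0.00511.

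At 2 h chaperone genes were still above their 0 min level, and histone genes stood high as well. HSP26 (Os03g0245800) was up by 11.75 ± 0.24 and HSP101 (Os05g0519700), which clears aggregates, by 3.92 ± 0.35. In the small heat shock list 21 of 27 rose, 1 fell and 5 did not pass (21 and 1 adjusted over the list alone, median 3.53, camera adjusted p = 6.44e-13). Of the chaperonins 19 of 28 rose, 2 fell and 7 did not pass (20 and 2 adjusted over the list alone, median 1.53, camera adjusted p = 3.87e-08), with CPN60-2 (Os05g0540300) at 4.57 ± 0.25 and Cpn21 (Os09g0438700) at 3.94 ± 0.19. Of the endoplasmic reticulum folding genes 11 of 15 rose and 4 did not pass (11 higher and 1 lower adjusted over the list alone, median 1.47, camera adjusted p = 4.26e-05), with BiP (Os05g0367800) at 2.83 ± 0.33. Of the histones, the proteins that package DNA, 34 of 46 rose, 2 fell and 10 did not pass (35 and 3 adjusted over the list alone, median 1.51, camera adjusted p = 6.44e-13); genes for H4 (Os03g0119900) and H2A (Os01g0502700) rose by 5.15 ± 0.39 and 3.81 ± 0.28. In the JAZ list 9 of 14 rose, 1 fell and 4 did not pass (10 and 2 adjusted over the list alone, median 1.89, camera adjusted p = 0.00348), with Os10g0391400 at 5.57 ± 0.54. Of the genes for galactinol, raffinose and trehalose synthesis 6 of 12 rose and 6 did not pass (6 adjusted over the list alone, median 0.93, camera adjusted p = 0.0193), and that call ended without 2 h replicate 1 (median 0.86, adjusted p = 0.0545). The membrane protein PM19 (Os05g0381400), described as induced by abscisic acid, rose by 9.68 ± 1.03, and the starch-degrading α-amylase (Os08g0473900) by 7.72 ± 0.69. In the starch and sucrose list 4 of 52 rose, 13 fell and 35 did not pass (4 and 9 adjusted over the list alone, median -0.23, or -0.20 with bounds, camera adjusted p = 0.47). The alternatives gave that median as -0.32 to -0.15. Methyl chloride transferase (Os03g0843800) fell by 6.78 ± 0.51 and phosphoethanolamine methyltransferase (Os05g0548900), of phosphocholine synthesis, by 6.06 ± 0.41. Of the WRKY factors 21 of 60 rose, 9 fell and 30 did not pass (21 and 9 adjusted over the list alone, median 0.37, camera adjusted p = 0.00902). Limma called 4621 genes higher and 5446 lower than at 0 min (2974 and 2744 at least 2-fold), and 3206 lower without 0 min replicate 1. Camera called 13 lists higher and 0 lower, with 1 lower at an unadjusted p under 0.05. The changed genes of this paragraph had adjusted p up to 4.79e-04.

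Between 1 h and 2 h, within a slide, heat shock factor genes mostly fell. Of the list 2 of 23 rose, 13 fell and 8 did not pass (2 and 14 adjusted over the list alone, median -0.86, camera adjusted p = 9.92e-04). The class A2 factor Os03g0745000 fell by 4.97 ± 0.30 and the gene described as Spl7 (Os04g0568700) fell by 3.20 ± 0.31. The comparison asked what had changed in the second hour. In the small heat shock list 1 of 27 rose, 12 fell and 14 did not pass (1 and 12 adjusted over the list alone, median -0.88, camera adjusted p = 0.0163), but the call ended under the 3 quantile scalings (medians -0.26 to -0.22, adjusted p 0.232 to 0.315). Of the histones 26 of 46 rose, 4 fell and 16 did not pass (27 and 4 adjusted over the list alone, median 0.65, camera adjusted p = 8.74e-04), and the median was 1.06 under quantile normalization and the authors' value table; a gene for H4 (Os04g0583600) rose by 4.17 ± 0.48 and 1 for H2B.2 (Os05g0460500) fell by 4.13 ± 0.52. Of the proteasome genes, for the protein-degrading complex, 21 of 54 rose, 1 fell and 32 did not pass (20 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.00195), and the median was 0.13 to 0.51 under the 3 quantile scalings and scaling on the median; subunit α3 (Os05g0490800) rose by 1.33 ± 0.19. The lowest genes included a metallothionein (Os05g0202800, -8.24 ± 1.69), from a family that binds metals, and methyl chloride transferase (Os03g0843800, -6.90 ± 0.51). The expansin gene Os10g0555600, for loosening cell walls, rose by 6.39 ± 1.28 but was well above background on only 1 of the 2 arrays at 1 h. In the cell wall list 32 of 106 rose, 14 fell and 60 did not pass (31 and 14 adjusted over the list alone, median 0.16, camera adjusted p = 0.308). Its median ran from -0.015 to 0.35 over the alternatives. The changed genes had adjusted p up to 0.00583. Limma called 5200 genes higher and 5339 lower (2470 and 3218 at least 2-fold), and 2991 higher and 3129 lower without 1 h replicate 1. With scaling on the median 3799 were higher and 6826 lower, as it shifted the median of all genes by -0.18. Camera called 6 lists, 10 without 2 h replicate 2, 11 without the filter on dim probes and 3 with each of the 3 quantile scalings.

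After 4 h, transcripts of ribosomal proteins and histones were mostly higher, and those of light harvesting and starch metabolism mostly lower, than at 0 min. Of the cytosolic ribosomal proteins, which build the machinery of translation, 212 of 243 rose, 5 fell and 26 did not pass (213 and 6 adjusted over the list alone, median 1.39, camera adjusted p = 8.93e-26). With the estimated correlation that adjusted p was 0.426. Genes for L21 (Os05g0557800) and S2 (Os07g0207400) rose by 3.77 ± 0.17 and 3.71 ± 0.22. The comparison asked what differed after longer heat. Of the histones 33 of 46 rose, 2 fell and 11 did not pass (35 and 2 adjusted over the list alone, median 1.89, camera adjusted p = 2.23e-09), with H2A (Os01g0502700) at 5.81 ± 0.28 and H4 (Os03g0119900) at 5.68 ± 0.39. Of the small heat shock proteins 20 of 27 rose, 3 fell and 4 did not pass (20 and 3 adjusted over the list alone, median 2.55, camera adjusted p = 2.85e-05), with HSP26 (Os03g0245800) at 10.98 ± 0.24, and of the chaperonins 23 of 28 rose, 3 fell and 2 did not pass (23 and 3 adjusted over the list alone, median 2.01, camera adjusted p = 6.46e-07), with CPN60-2 (Os05g0540300) at 5.33 ± 0.25. Of the endoplasmic reticulum folding genes 11 of 15 rose, 1 fell and 3 did not pass (12 and 1 adjusted over the list alone, median 1.39, camera adjusted p = 0.00535), with calreticulin (Os03g0832200) at 3.52 ± 0.69. Other large rises were those of a thiazole synthesis enzyme (Os07g0529600, 7.45 ± 0.38), needed for vitamin B1, and an RNA-binding protein (Os01g0916600, 8.10 ± 0.97). The highest adjusted p among the changed genes of this paragraph was 0.00323.

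Of the light harvesting and photosystem genes at 4 h, 3 of 46 rose, 37 fell and 6 did not pass (3 and 38 adjusted over the list alone, median -1.09, camera adjusted p = 6.24e-08). PsbS (Os01g0869800), which sheds excess light energy, fell by 6.37 ± 0.84, PsbW (Os01g0938100) by 3.52 ± 0.63 and photosystem I subunit N (Os05g0242400) by 3.34 ± 0.24. The call ended under quantile normalization and the authors' value table (medians -0.41, adjusted p 0.0687 to 0.071), and the median was -0.48 under normexp with quantile normalization. In the Calvin cycle list 7 of 30 rose, 19 fell and 4 did not pass (7 and 20 adjusted over the list alone, median -1.15, camera adjusted p = 0.0145); sedoheptulose bisphosphatase (Os04g0234600), of carbon fixation, fell by 3.20 ± 0.25, while those that rose included genes for Rubisco-binding chaperonins, which fold Rubisco (Os12g0277500, 2.66 ± 0.17, and Os03g0859700, 2.31 ± 0.39). That call ended under the 3 quantile scalings (medians -0.68 to -0.60, adjusted p 0.154 to 0.21). Of the starch and sucrose genes 5 of 52 rose, 28 fell and 19 did not pass (5 and 28 adjusted over the list alone, median -0.66, or -0.65 with bounds, camera adjusted p = 0.00186), with granule-bound starch synthase (Os07g0412100), which makes amylose, at -6.05 ± 0.28, a β-amylase (Os10g0465700) at -4.13 ± 0.89 and α-amylase (Os08g0473900) at 7.40 ± 0.69. Of the chlorophyll synthesis genes 3 of 21 rose, 10 fell and 8 did not pass (3 and 10 adjusted over the list alone, median -0.41, camera adjusted p = 0.15), with Mg-chelatase (Os07g0656500), at the branch to chlorophyll, at -3.17 ± 0.41. The median of that list ran from -0.73 to -0.21 over the alternatives. Of the splicing factors 14 of 36 rose, 3 fell and 19 did not pass (14 and 3 adjusted over the list alone, median 0.29, camera adjusted p = 0.0193), a call that ended under scaling on the median, no filter on dim probes and only probes well above background on all 12 arrays and without 0 min replicate 1 and 4 h replicate 1 (medians 0.057 to 0.29, adjusted p 0.05 to 0.146). Of the auxin response genes 11 of 52 rose, 15 fell and 26 did not pass (11 and 14 adjusted over the list alone, median -0.19, or -0.15 with bounds, camera adjusted p = 0.583), with a SAUR gene (Os08g0452500) at 4.87 ± 0.56. Their median ran from -0.42 to -0.14 over the alternatives. A Dof-type regulator (Os01g0264000) and an S41 peptidase (Os02g0815700) were among the lowest, at -6.53 ± 0.27 and -6.22 ± 0.17. The changed genes had adjusted p up to 0.0048. Limma called 6559 genes higher and 6332 lower (4392 and 3765 at least 2-fold), and camera called 6 lists higher and 3 lower. With scaling on the median 5160 were higher and 8301 lower, as it shifted the median of all genes by -0.23, and without the filter on dim probes 10198 were higher.

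At 8 h ribosomal protein genes were still high, and granule-bound starch synthase stood far below its 0 min level. Of the cytosolic ribosomal proteins 216 of 243 rose, 5 fell and 22 did not pass (218 and 6 adjusted over the list alone, median 1.43, camera adjusted p = 1.82e-26), with L21 (Os05g0557800) at 4.17 ± 0.17. Camera's adjusted p was 0.671 with the estimated correlation. Granule-bound starch synthase (Os07g0412100) fell by 8.00 ± 0.28, while α-amylase (Os08g0473900) rose by 8.09 ± 0.69 and sucrose synthase SUS2 (Os03g0401300), which splits sucrose, by 3.54 ± 0.33. Of the starch and sucrose list 7 of 52 rose, 25 fell and 20 did not pass (7 and 26 adjusted over the list alone, median -0.57, or -0.52 with bounds, camera adjusted p = 0.0129). The comparison asked what differed after the longest heat. Among small heat shock proteins 18 of 27 rose, 4 fell and 5 did not pass (18 and 4 adjusted over the list alone, median 1.70, camera adjusted p = 0.00154). Of the chaperonins 21 of 28 rose, 2 fell and 5 did not pass (21 and 3 adjusted over the list alone, median 1.85, camera adjusted p = 2.84e-06). Of the histones 24 of 46 rose, 4 fell and 18 did not pass (25 and 4 adjusted over the list alone, median 0.71, camera adjusted p = 0.0015). HSP26 (Os03g0245800) was up by 10.20 ± 0.24, CPN60-2 (Os05g0540300) by 4.72 ± 0.25 and the heat shock factor Hsf29 (Os01g0733200) by 8.79 ± 0.74. In the heat shock factor list 10 of 23 rose, 7 fell and 6 did not pass (10 and 8 adjusted over the list alone, median 0.25, camera adjusted p = 0.584). That median ran from 0.017 to 0.71 over the alternatives. Of the light harvesting and photosystem genes 3 of 46 rose, 38 fell and 5 did not pass (3 and 40 adjusted over the list alone, median -1.23, camera adjusted p = 1.60e-08), with PsbS (Os01g0869800) at -5.60 ± 0.84; the call ended under quantile normalization and the authors' value table (medians -0.47, adjusted p 0.0523 to 0.0535) and the median was -0.43 under normexp with quantile normalization. Protochlorophyllide reductase PORA (Os04g0678700), for the light-driven step to chlorophyll, fell by 4.60 ± 0.94. In the chlorophyll synthesis list 5 of 21 rose, 9 fell and 7 did not pass (5 and 9 adjusted over the list alone, median -0.23, camera adjusted p = 0.473). Over the alternatives the median ran from -0.47 to -0.055. A gene described as isocitrate lyase and phosphorylmutase (Os12g0189300) fell by 8.25 ± 0.58 and a CorA-like magnesium transporter (Os03g0684400) fell by 7.67 ± 0.27. The plastid sigma factor SIG5 (Os05g0586600), which directs transcription in chloroplasts, fell by 8.87 ± 0.85 but was well above background on only 1 of the 2 arrays at 8 h. The changed genes had adjusted p up to 0.00369. Limma called 6443 genes higher and 6129 lower than at 0 min (4342 and 3716 at least 2-fold), and camera called 5 lists higher and 4 lower. With scaling on the median 5098 were higher and 8168 lower, as it shifted the median of all genes by -0.23, and without the filter on dim probes 9891 were higher.

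Between 4 h and 8 h, within a slide, a part of the histone and JAZ genes fell. Of the histones 1 of 46 rose, 19 fell and 26 did not pass (1 and 28 adjusted over the list alone, median -0.78, camera adjusted p = 4.42e-13), with H4 (Os03g0119900) down by 2.84 ± 0.39 in log2. In the JAZ list 8 of 14 fell and 6 did not pass (10 adjusted over the list alone, median -1.43, camera adjusted p = 1.35e-06), with Os03g0181100 at -4.46 ± 0.41 and Os10g0391400 at -3.94 ± 0.54. Another of those that fell, Os02g0245800, encodes a potassium channel rather than a JAZ protein. The comparison asked what had changed late in the heat. Among small heat shock proteins 9 of 27 fell and 18 did not pass (13 adjusted over the list alone, median -0.58, camera adjusted p = 7.46e-06), with Os01g0136100 at -3.63 ± 0.43 and Os01g0136200 at -3.15 ± 0.52, and the median was -1.06 without 8 h replicate 1. An amino acid or polyamine transporter (Os01g0597600) fell by 5.32 ± 0.69, while a Myb-type clock regulator (Os01g0971800) rose by 4.41 ± 0.57. In the circadian clock list 2 of 12 rose, 1 fell and 9 did not pass (2 and 1 adjusted over the list alone, median 0.030, camera adjusted p = 0.747). Over the alternatives its median ran from -0.069 to 0.13. The changed genes had adjusted p up to 0.0127. Limma called 928 genes higher and 1250 lower (463 and 914 at least 2-fold); under the 3 quantile scalings 1418 to 1711 were higher, and without the filter on dim probes 504. Both counts depended on the arrays used: they were 0 and 0 when limma was fitted to these 4 arrays alone (4434 genes at an unadjusted p under 0.05), 305 and 525 without 4 h replicate 2, 346 and 532 without 8 h replicate 1, and 325 and 562 without 8 h replicate 2. The higher count was also 589 without either 0 min array, 593 without either 20 min array and 562 without either 1 h array. Camera called 10 lists lower, 6 without 4 h replicate 1, and 0 higher, also at an unadjusted p under 0.05.

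From 20 min to 8 h, genes for small heat shock proteins and heat shock factors mostly fell, while ribosomal protein genes mostly rose. Of the small heat shock proteins 2 of 27 rose, 23 fell and 2 did not pass (2 and 23 adjusted over the list alone, median -2.81, camera adjusted p = 2.99e-06). The Hsp20-type gene Os02g0711300 fell by 11.08 ± 0.45 and was well above background on only 1 of the 2 arrays at 8 h. Of the heat shock factors 2 of 23 rose, 19 fell and 2 did not pass (2 and 19 adjusted over the list alone, median -2.40, camera adjusted p = 2.99e-06), with Os06g0565200 at -9.58 ± 0.26 and Hsf29 (Os01g0733200) at 6.83 ± 0.74. The comparison asked how the late response differed from the early one. Of the HSP100 and ClpB genes 3 of 3 fell (3 adjusted over the list alone, median -5.21, camera adjusted p = 0.015). In the JAZ list 13 of 14 fell and 1 did not pass (13 adjusted over the list alone, median -2.70, camera adjusted p = 1.19e-04). Of the cytosolic ribosomal proteins 216 of 243 rose, 11 fell and 16 did not pass (217 and 12 adjusted over the list alone, median 1.42, camera adjusted p = 1.12e-17), with L11 (Os10g0466200) at 4.46 ± 0.31. The estimated correlation gave that list an adjusted p of 0.391. Of the aquaporins 7 of 10 fell and 3 did not pass (7 adjusted over the list alone, median -2.27, camera adjusted p = 0.0102), with the water channel gene Os02g0823100 at -5.92 ± 0.62; the call ended under quantile normalization and the authors' value table (medians -1.44 to -1.43, adjusted p 0.108) and the median was -1.02 under normexp with quantile normalization. Of the starch and sucrose genes 8 of 52 rose, 29 fell and 15 did not pass (8 and 29 adjusted over the list alone, median -0.80, camera adjusted p = 0.0116), with granule-bound starch synthase (Os07g0412100) at -8.76 ± 0.28, and the median was -0.50 under normexp with quantile normalization. The changed genes had adjusted p up to 6.53e-05. Limma called 8217 genes higher and 7474 lower (5835 and 5655 at least 2-fold). With scaling on the median 6496 were higher and 9318 lower, as it shifted the median of all genes by -0.31.

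**Figure D2:**
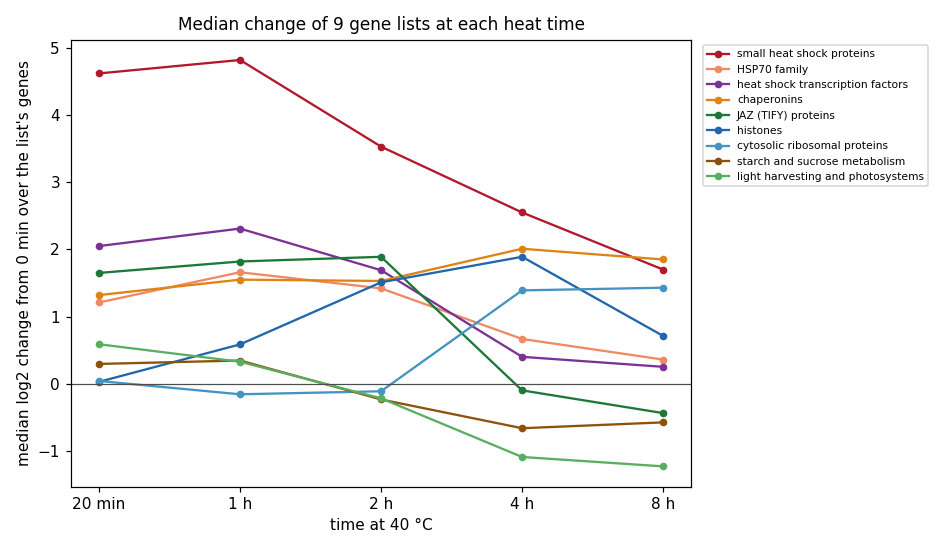
Median log2 fold change against 0 min of 9 gene lists at the 5 heat times, with 1 line per list. Small heat shock proteins fell from a median of 4.82 at 1 h to 1.70 at 8 h and ribosomal proteins stood at 1.39 and 1.43 at 4 h and 8 h, while the signs of light harvesting at 20 min and 1 h, of histones and ribosomal proteins at 20 min and of JAZ at 4 h turned with the 3 quantile scalings.

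Of the 8 genes followed at every time, the class A2 heat shock factor Os03g0745000, a regulator of heat shock genes, was not well above background at 0 min and was at least 11273-fold higher at 20 min, at least 11798-fold at 1 h, at least 375-fold at 2 h, at least 33.1-fold at 4 h and at least 61-fold at 8 h (adjusted p up to 1.13e-05). HSP101 (Os05g0519700), saturated at 1 h, was at least 33.8-fold higher (adjusted p = 2.09e-05) then, while at 4 h and 8 h its values were 0.34 ± 0.35 (adjusted p = 0.428) and -0.025 ± 0.35 (adjusted p = 0.959). Its 8 h value turned to 0.61 (adjusted p = 0.0413) without 8 h replicate 2 and was -0.66 (adjusted p = 0.0312) without 8 h replicate 1. A further class A2 factor (Os03g0795900) rose by 1.32 ± 0.15 at 20 min and fell by 0.66 ± 0.15 at 4 h (adjusted p = 0.00706, or 0.0563 with only the 4 arrays compared). Actin 1 (Os03g0718100), a cytoskeletal gene often used as a reference, rose by 2.38 ± 0.23 at 20 min and 2.43 ± 0.23 at 1 h and had 0.24 ± 0.23 (adjusted p = 0.425) at 8 h. Ascorbate peroxidase APX2 (Os07g0694700), which removes hydrogen peroxide, rose by 1.66 ± 0.14 at 20 min and fell by 0.69 ± 0.14 at 4 h. Rubisco activase (Os11g0707000), which frees Rubisco from inhibitors, was saturated at 0 min and at least 2.97-fold lower (adjusted p = 7.20e-04) at 4 h and at least 6.21-fold lower (adjusted p = 4.61e-05) at 8 h. The clock gene LHY (Os08g0157600), a morning gene, fell, with -1.31 ± 0.27 at 2 h, -6.24 ± 0.27 at 4 h and -7.52 ± 0.27 at 8 h. TOC1 (Os02g0618200), an evening gene, rose by 2.02 ± 0.31, 5.45 ± 0.31 and 5.21 ± 0.31 at those times. Of the circadian clock list at 8 h 6 of 12 rose, 4 fell and 2 did not pass (7 and 4 adjusted over the list alone, median 0.51, camera adjusted p = 0.597). Its median there ran from 0.27 to 0.85 over the alternatives.

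**Figure D3:**
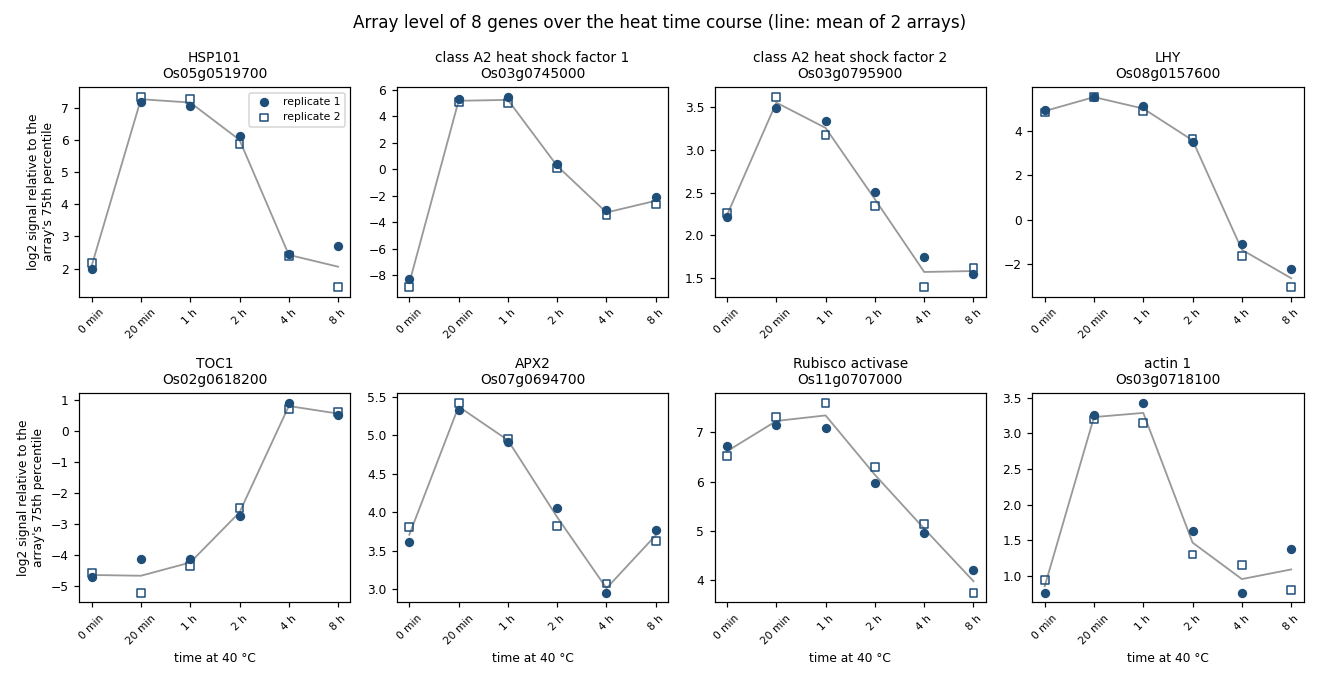
Log2 level of the 8 genes followed at every time, relative to each array's 75th percentile, with filled circles for replicate 1, open squares for replicate 2 and lines through the means of the 2 arrays. LHY stood at 4.96 and 4.82 at 0 min and at -2.24 and -3.03 at 8 h, Os03g0745000 was not well above background at 0 min, and HSP101 was saturated at 20 min and 1 h.

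Markers of spikelet tissue and common reference genes were followed as well. Changes of the markers cannot show which tissue was sampled, as the labels give all arrays the same one. Of the floral organ MADS genes on the array 7 of 12 were measured, and of the anther and pollen markers 7 of 13. Of the floral organ MADS genes, which set organ identity in the flower, 2 of 7 fell and 5 did not pass (1 adjusted over the list alone, median -0.56, camera adjusted p = 0.523) at 4 h, with SPW1 (Os06g0712700) at -1.41 ± 0.24. Of the anther and pollen markers 4 of 7 rose, 1 fell and 2 did not pass (4 and 1 adjusted over the list alone, median 0.91, camera adjusted p = 0.15), with a cytochrome P450 (Os03g0168600) at 0.91 ± 0.18. Of the reference genes 2 of 4 rose, 1 fell and 1 did not pass (2 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.678), with ubiquitin (Os01g0328400) at 1.10 ± 0.16. Over the alternatives the medians of these 3 lists ran from -0.79 to -0.35, 0.43 to 1.10 and 0.087 to 0.71. The 3 genes named had adjusted p up to 0.00304.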

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

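The tests of time of day and of genes nearest in signal, and the look at the microRNA probes, were chosen after the results were seen; the random lists matched on mean signal were planned before. The 3 lists below did not pass with camera's estimated correlation (adjusted p = 0.351, 0.351 and 0.224).

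Light harvesting and photosystem genes, whose proteins capture light, stood above 0 min at 20 min (median 0.59, against 0.64 for the genes nearest in signal, and turned to -0.12 to -0.10 under the 3 quantile scalings) and below it at 8 h (median -1.23), and drew attention because the direct comparison of 8 h with 20 min gave a median of -1.85 (camera adjusted p = 1.43e-08, medians -2.16 to -0.18 and adjusted p 1.97e-11 to 0.351 over its alternatives). A shift shared by bright genes was present: the 50 genes nearest in mean signal to each member had a median of -1.79, and the call ended under the 3 quantile scalings (medians -0.20 to -0.18, adjusted p 0.116 to 0.13). The lowest median of 10000 random lists from 20 wide bins of signal was -0.979, above the list's -1.09 at 4 h and -1.23 at 8 h. The genes nearest in signal fell less than the list, with medians of -0.66 and -0.95, and lists drawn from them reached -1.08 and -1.21, which the list only just passed. With any 1 of the 4 h and 8 h arrays left out the lowest such list lay below it at both times, as at 4 h without 4 h replicate 2 (-1.11 against -1.03) and at 8 h without 8 h replicate 2 (-1.30 against -1.27), while without 0 min replicate 2 it lay above it at both, so a brightness shift as the whole cause stays open. LHY, a morning clock gene, fell by 7.52 by 8 h (Os08g0157600), so heat and time of day cannot be told apart, and the slide also differed between these times. What stays open is a brightness shift, the time of day, the slide, or, untested, a response of these genes to heat, which could each give the lower values.

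The Calvin cycle genes, which fix carbon, drew attention by the same direct comparison, with a median of -1.29 (camera adjusted p = 0.0128, medians -1.60 to -0.015 and adjusted p 0.00143 to 0.568 over its alternatives), against -0.93 for the genes nearest in signal, and the call ended under the 3 quantile scalings (medians -0.029 to -0.015, adjusted p 0.546 to 0.568). The aquaporins, which carry water through membranes, did so with a median of -2.27 (camera adjusted p = 0.0102, medians -2.61 to -1.02 and adjusted p 0.00143 to 0.224 over its alternatives), against -0.50 for the genes nearest in signal, and the call ended under quantile normalization and the authors' value table (medians -1.44 to -1.43, adjusted p 0.108). Probes named for microRNAs carried a signal outside the gene comparisons, as limma called 83 of 270 higher and 18 lower at 20 min than at 0 min. Over the 4 other scalings 58 to 95 were higher, without 0 min replicate 2 it was 51, and without 0 min replicate 1 the lower count was 11.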

How the results depend on the processing

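The fit without the 4 h and 8 h arrays was added after the data were seen, as was leaving arrays out of the tests of slides and of genes nearest in signal, and all other alternatives were planned. Limits were the 2 arrays per time, dim probes, and slide and time of day, which moved with heat time. Of the 138 values of genes named in the report, 138 kept direction and side of the threshold under each of the 4 other scalings, no filter on dim probes, the mean of a gene's probes, outlier-flagged spots kept, the replicate block and the trend and robust prior, and 114 of 114 did with only probes well above background on all 12 arrays. With only the 4 arrays compared 8 of 138 missed the threshold, where fewer arrays estimate the spread, and 4 changed less than 2-fold. With 1 array left out all but 1 of the 138 values kept both in every case. The exception was HSP101 (Os05g0519700) at 8 h, which ran from -0.66 to 0.61, with the sign set by which 8 h array was left out. This stability holds for the named genes only. Some of the 6 highest or lowest genes of a comparison lost their call without 1 array and were not named there. Most of the 6 lowest at 20 min were among them.

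The higher count of 928 for 8 h versus 4 h became 1711 with normexp and quantile normalization, 1433 with quantile normalization, 1418 with the authors' value table and 504 without the filter on dim probes, and the cause was not tested. With only the 4 arrays compared limma called 0 higher and 0 lower (4434 at an unadjusted p under 0.05), with 2 residual degrees of freedom in place of 6. Without the filter on dim probes 10198 genes were higher at 4 h and 9891 at 8 h. The lowest signal of an array was 43.6 to 54.86 at 4 h and 8 h, against 6.058 and 10.02 at 0 min. The 75th percentile differed less, at 10520 to 11660 against 6110 and 8093. Such a floor lifts dim probes after scaling, and how many of these calls it explains was not tested. With the 2-fold threshold the higher counts that moved were 2974 (2 h), 2470 (2 h versus 1 h) and 463 (8 h versus 4 h), and the lower ones 2997 (20 min), 3814 (1 h), 2744 (2 h), 3765 (4 h), 3716 (8 h) and 3218 (2 h versus 1 h), as smaller changes no longer counted. With 1 array left out, where the lone array of a time is assumed to vary like the others, the counts that moved over 1.5 times ran as follows: lower at 20 min 3746 to 6083, lower at 2 h 3206 to 5786, 2 h versus 1 h higher 2991 to 5516 and lower 3129 to 5630, 8 h versus 4 h higher 305 to 1075 and lower 525 to 1410. The count of the F-test ran from 19253 to 20584. Median scaling shifted the median of all genes by -0.23 at 4 h, -0.23 at 8 h, -0.18 for 2 h versus 1 h and -0.31 for 8 h versus 20 min without moving a count over 1.5 times.

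The median of light harvesting turned from 0.59 to -0.10 with normexp and quantile normalization, -0.12 with quantile normalization and -0.12 with the authors' value table at 20 min, from 0.33 to -0.19, -0.22 and -0.22 at 1 h, and from -0.54 to 0.12, 0.13 and 0.13 for 2 h versus 1 h. Before these scalings the genes nearest in signal, outside the list, had medians of 0.64, 0.54 and -0.69 there. A shift shared by bright genes was thus present, and whether the quantile scalings remove it from those genes was not tested. Over the 256 list results, the 3 quantile scalings ended 19, 22 and 22 calls without a turn of direction, turned and ended 3 more each (light harvesting) and added 13, 12 and 12, median scaling ended 9, no filter on dim probes ended 8 and added 13, and the strict filter, which left 30 of the 32 lists to test, ended 11 and added 8 of its fewer results. Camera's count for 2 h versus 1 h was 3 with normexp and quantile normalization, 3 with quantile normalization, 3 with the authors' value table and 11 without the filter on dim probes. With the 2-fold threshold on the median the counts were 9 (20 min), 10 (1 h), 0 (2 h versus 1 h, where 2 higher and 10 lower had an unadjusted p under 0.05 without that threshold) and 2 (8 h versus 4 h). With 1 array left out the counts that moved ran 6 to 10 (2 h versus 1 h) and 6 to 10 (8 h versus 4 h). With an estimated correlation camera called 0 lists in each of the 8 comparisons, and at an unadjusted p under 0.05 it called 7 (20 min), 9 (1 h), 6 (2 h), 2 (4 h), 3 (8 h), 1 (2 h versus 1 h), 2 (8 h versus 4 h) and 5 (8 h versus 20 min). The fit without the 4 h and 8 h arrays moved 0 of 8 gene counts over 1.5 times.

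The values showed no strong pairing of the arrays by replicate number, which cannot show how the replicate experiments were run. The deviations of arrays with the same number correlated across genes, which are not independent, at -0.188 to 0.15 over 15 pairs of times (median -0.0458). With the replicate number as a block 0 gene counts moved over 1.5 times, 1 list call ended (light harvesting, 8 h versus 4 h, adjusted p = 0.0502, medians -0.25 to 0.024 and adjusted p 0.00611 to 0.883 over its alternatives) and 2 were added. Spike-in scaling and a slide term were not run.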

Other observations

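Probes, gene families and the names picked from them in the next paragraphs were chosen after their values were seen, as were all tests of slides below; the random lists for ribosomal proteins were planned before.

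Among probes named for microRNAs, short RNAs that silence genes, some changed by large amounts. They were read from labelled cRNA, and whether they report mature microRNAs, precursors or other transcripts was not tested. Their values are probe signals, not levels of the microRNAs they are named for. A probe for the miR398b precursor, whose mature form targets superoxide dismutase transcripts, gave -5.36 ± 1.06 at 20 min and -5.86 ± 1.06 at 1 h. The mature-sequence probe of miR408, which targets copper proteins, gave -3.23 ± 0.61, -3.34 ± 0.61, -3.34 ± 0.61 and -3.58 ± 0.61 from 20 min to 4 h, and a miR528 precursor probe -5.33 ± 1.16 at 1 h. The miR169b precursor, of a family that targets NF-YA factors, stood at 4.12 ± 0.34 at 20 min and 3.04 ± 0.34 at 1 h, and that of miR399d, which acts on phosphate balance, at 6.37 ± 0.39 and 5.49 ± 0.39. Later in the heat the mature-sequence probe of miR160a, which targets auxin response factors, fell by 1.72 ± 0.26, 2.31 ± 0.26 and 2.97 ± 0.26 at 2 h, 4 h and 8 h, and a precursor probe of miR168a, which targets AGO1, fell by 2.22 ± 0.16 and 2.53 ± 0.16 at 4 h and 8 h. The highest adjusted p of these was 0.00504, and the signs and calls held under the 4 other scalings and with each array left out. Of 510 such probes 270 were kept. From 1 h to 2 h, within a slide, 7 of these rose and 125 fell, or 3 and 77 without 1 h replicate 1, and 12 rose without either 4 h array. Counts for 1 h to 8 h against 0 min moved over 1.5 times when 1 array was left out and are not given. Array signal also differed between 1 h and 2 h, with 75th percentiles of 4059 and 4749 against 7629 and 8309. Its part in the counts from 1 h to 2 h was not tested.

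Among 71 groups of at least 20 genes that share a description, some moved one way early and the other way late. Genes described by a protein prenyltransferase domain, an entry that also matches helical repeat proteins of organelle RNA processing, were low at 20 min, where 12 of 129 rose and 60 fell (median -0.59, -0.61 to -0.45 over the 4 other scalings, camera adjusted p = 0.0041), and high at 8 h, where 87 of 129 rose and 7 fell (median 1.14, 0.88 to 0.98 over the 4 other scalings, camera adjusted p = 7.47e-09). Against 20 min, 103 of 129 rose and 7 fell (median 1.88, 1.43 to 1.72 over the 4 other scalings, camera adjusted p = 1.33e-10) at 8 h. Of the genes with a TPR-like domain, which mediates protein contacts, 168 of 299 rose and 28 fell (median 1.04, 0.68 to 0.89 over the 4 other scalings, camera adjusted p = 4.14e-08) at 8 h. Of the mitochondrial transcription termination factor-related genes, which act on organelle transcripts, 15 of 29 fell and 0 rose (median -0.55, -0.63 to -0.48 over the 4 other scalings, camera adjusted p = 0.00929) at 20 min and 22 of 29 rose and 2 fell (median 1.30, 0.95 to 1.16 over the 4 other scalings, camera adjusted p = 8.18e-04) from 20 min to 8 h. Of the FAR1 genes, known for phytochrome signalling, 1 of 23 rose and 19 fell (median -0.79, -0.74 to -0.65 over the 4 other scalings, camera adjusted p = 3.65e-04) at 20 min, and within the second slide 17 of 23 rose and 1 fell (median 0.74, 0.56 to 0.61 over the 4 other scalings, camera adjusted p = 2.55e-04) from 1 h to 2 h. Of the U box genes, for ubiquitin ligases, 19 of 40 rose and 4 fell (median 0.73, 0.46 to 0.81 over the 4 other scalings, camera adjusted p = 0.00929) at 20 min, and at 1 h 28 of 51 rose and 9 fell (median 1.23, 0.71 to 1.32 over the 4 other scalings, camera adjusted p = 0.00157) of the genes with a heavy metal transport domain. With the estimated correlation the adjusted p of these groups lay between 0.159 and 0.673. The groups were not set against the genes nearest in signal, so a shift shared by genes of similar signal stays open for them. In the comparisons across slides, at 1 h, at 8 h and of 8 h with 20 min, slide, time of day and heat time cannot be told apart.

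The rise of cytosolic ribosomal protein genes at 4 h and 8 h (medians 1.39 and 1.43) was weighed against 2 technical explanations. The values argue against a shift shared by probes of this brightness, as the highest median among 10000 random lists matched on mean signal was 0.0949 and the 50 genes nearest in signal had medians of -0.15 and -0.19. Within the third slide the list changed by a median of 0.063 from 4 h to 8 h, so the rise lies between slides, and slide, time of day and heat time cannot be told apart there, because that slide holds only these times. A late rise of transcripts for the translation machinery in heat may remain as a biological explanation, which was not tested.

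The 20 min and 1 h arrays stood apart from the 4 h and 8 h arrays on the first principal component. Array signal followed the same order. Its 75th percentile was 4059 to 4749 at 20 min and 1 h, 6110 to 8309 at 0 min and 2 h, and 10520 to 11660 at 4 h and 8 h. Signal and heat time therefore cannot be told apart on this component. Among the first 2 slides the values argue against the slide as the main source of differences: 4455 genes differed between 1 h and 20 min, across slides (2436 higher and 2019 lower), and more did between 2 h and 1 h within a slide (5200 and 5339). The first count was 1578 and 943 without 20 min replicate 1 and 2 and 1679 and 545 without 1 h replicate 1 and 2, and the second, over both directions, was 6120 without 1 h replicate 1; the second stayed higher with each of the 12 arrays left out. Signal was alike at 20 min and 1 h but higher at 2 h, so the larger count within a slide may follow signal. This was not tested. Between 4 h and 2 h, across slides, 10435 genes differed (5588 higher and 4847 lower), and since the third slide holds only 4 h and 8 h arrays, slide and heat time cannot be told apart there. Its arrays had the smallest shares of spots well above background, 65.3 to 68.4%, so a part of its difference could come from the slide. A change of the leaf transcripts with heat or time of day stays open as well and was not tested apart from it.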
